A study of Homo sapiens with 6 samples.

How the data were processed

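Expression was measured in 6 samples of the L428 Hodgkin lymphoma cell line, 3 transfected with a miR-9 LNA inhibitor and 3 with a scrambled LNA, with RNA taken 9 h later, per the labels. The authors hybridized total RNA to Affymetrix HG-U133 Plus 2.0 arrays and deposited log2 values made with affy and RMA, per the submitters' processing notes, with versions and further options not given in the sources used here. The lowest deposited log2 value lay near 6 on each array, and whether an offset was added beyond RMA is not given in the sources used here. The series text names limma after removal of uninformative genes, without a threshold for that removal. No genome build applies to these values.

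From the deposited log2 values, 62 control probe sets were left out of the 54675, and the 27307 probe sets with a mean over the 6 arrays at or above the median of all remaining probe sets (7.11) were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe sets below the filter for ELAVL1 and DICER1 were read from a limma fit without the filter. Gene names came from the platform annotation: 41091 probe sets had 1 gene symbol, 1801 several and 11721 none, and probe sets with several or none were tested and not named. Of those with 1 symbol, 41037 matched the GRCh38.p14 gene table by Entrez ID and 54 did not, and 0 symbols needed updating. The gene table served for names and gene length only. Probe sets of opposite direction, each at an unadjusted p under 0.05, were found for 10 genes.

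Gene lists were tested with limma camera at a preset correlation of 0.01, on the brightest tested probe set of each of 12367 genes, with Benjamini-Hochberg adjustment over 30 lists of at least 5 tested members. Of 945 listed genes, 90.1% were named on the array. Each list's median was set against 10000 random lists matched on level in 20 bins, a comparison added after the data were examined. Single values per array were compared by two-sided exact permutation tests, for which 3 against 3 arrays give no p below 0.1.

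The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule names each probe set of ELAVL1 and DICER1, then the 12 genes of largest change in each direction past the threshold or, where none pass, the 8 genes of smallest p in each direction, then up to 3 members of smallest p of each list. Genes named outside this rule are said to be so or serve as descriptions of a list: PRDM1, CCL17, CCL5 and CCL1 were chosen after their values were seen. A test of miR-9 seed sites in 3' UTRs had been planned and was not run, as 3' UTR sequence was not used here.

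The replicate numbers come from the labels, which do not say what a number shares. Deviations from the group means correlated between same-numbered arrays at r = 0.231, 0.193 and 0.634 across probe sets, and between arrays of other numbers at -0.429 to 0.168, so the pairing comes from the data. Alternatives covered the filter, normalization between arrays, the variance model, array weights, the replicate block, a 3'-minus-5' covariate, the probe set to gene rule, the fold threshold, the set test and leaving out each array. The scripts were tested on simulated data, where limma called 16 of 26707 unchanged probe sets, and camera called the 1 list shifted by a log2 of 0.2 and 0 unshifted lists. The simulated probe sets varied independently of each other. These counts therefore do not give error rates for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.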

Results

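Expression was measured in L428, an established cell line of Hodgkin lymphoma, after transfection with a locked nucleic acid (LNA) inhibitor of the microRNA miR-9 or with a scrambled LNA. Total RNA was taken 9 h after transfection and hybridized to 6 Affymetrix HG-U133 Plus 2.0 arrays, 3 per group. The deposited values are log2 RMA expression for 54675 probe sets, with array medians between 7.10 and 7.15. Precision is limited by the number of arrays. The labels number the replicates but do not say whether they were separate cultures, so p-values measure the spread between samples. Errors of log2 differences are standard errors from limma and errors of group means are SDs, each with n = 3 arrays per group. Differences are the miR-9 LNA minus the scrambled LNA. The lowest value on each array lay near 6, higher than RMA alone usually leaves, so differences of dim genes may be understated.

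The series title names HuR (ELAVL1), an RNA-binding protein that stabilizes mRNAs, and DICER1, the nuclease that matures microRNAs, as regulated when miR-9 is inhibited. If miR-9 lowers the mRNAs of both genes, their levels should lie higher with the inhibitor. The arrays read mRNA at 9 h and not protein, so regulation of protein alone would not appear here. ELAVL1 mRNA was modestly higher with the miR-9 LNA in the deposited values, and the size of that difference was shared by other bright genes. The DICER1 probe sets gave differences of both signs. No probe set of either gene passed the threshold.

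ELAVL1 was read by 4 probe sets. At 201726_at its level was 11.64 ± 0.13 with the miR-9 LNA and 11.40 ± 0.18 with the scrambled LNA, a log2 difference of 0.24 ± 0.11 (limma adjusted p = 0.362), and the arrays of the groups overlapped. At 201727_s_at ELAVL1 was at 9.78 ± 0.03 and 9.57 ± 0.14, a log2 difference of 0.21 ± 0.08 (limma adjusted p = 0.318). Leaving out each array in turn, that difference ranged from 0.13 (without scrambled replicate 1) to 0.26 (without scrambled replicate 2). All 3 miR-9 LNA arrays lay above all 3 scrambled arrays for this probe set, for which a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. ELAVL1 probe sets 227746_at and 244660_at lay closer to the background, with log2 differences of 0.09 ± 0.07 and 0.11 ± 0.11 (limma adjusted p = 0.574 and 0.724), the latter below the level filter. After quantile normalization the ELAVL1 differences at 201726_at and 201727_s_at were 0.04 and 0.05. Within the same-numbered pairs of arrays, ELAVL1 probe sets 201726_at and 201727_s_at were higher with the miR-9 LNA in 3 of 3 pairs, and 227746_at and 244660_at in 2 of 3.

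DICER1 was read by 6 probe sets. At 212888_at DICER1 was at 9.01 ± 0.08 with the miR-9 LNA and 8.81 ± 0.02 with the scrambled LNA, a log2 difference of 0.20 ± 0.06 (limma adjusted p = 0.296). The arrays of the groups did not overlap at 212888_at (exact permutation p = 0.1, two-sided), and its difference after quantile normalization was 0.07. The brightest DICER1 probe set, 213229_at, was at 10.21 ± 0.31 and 10.37 ± 0.42, a log2 difference of -0.16 ± 0.23 (limma adjusted p = 0.750). DICER1 probe set 206061_s_at differed by -0.01 ± 0.20 (limma adjusted p = 0.981). After quantile normalization the differences were -0.35 at 213229_at (limma unadjusted p = 0.0816) and -0.11 at 206061_s_at. The SDs of 213229_at and 206061_s_at exceeded their differences in the deposited values, and scrambled replicate 1 lay lowest among the 6 arrays at both. At 213229_at it was nearly level with miR-9 LNA replicate 2 (9.896 against 9.898). Within the same-numbered pairs, DICER1 was higher with the miR-9 LNA in 3 of 3 pairs at 212888_at and in 1 of 3 at 213229_at and 206061_s_at. DICER1 probe sets 216260_at, 216280_s_at and 216281_at lay below the level filter, with log2 differences of 0.05, -0.08 and -0.04.

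**Figure D1:**
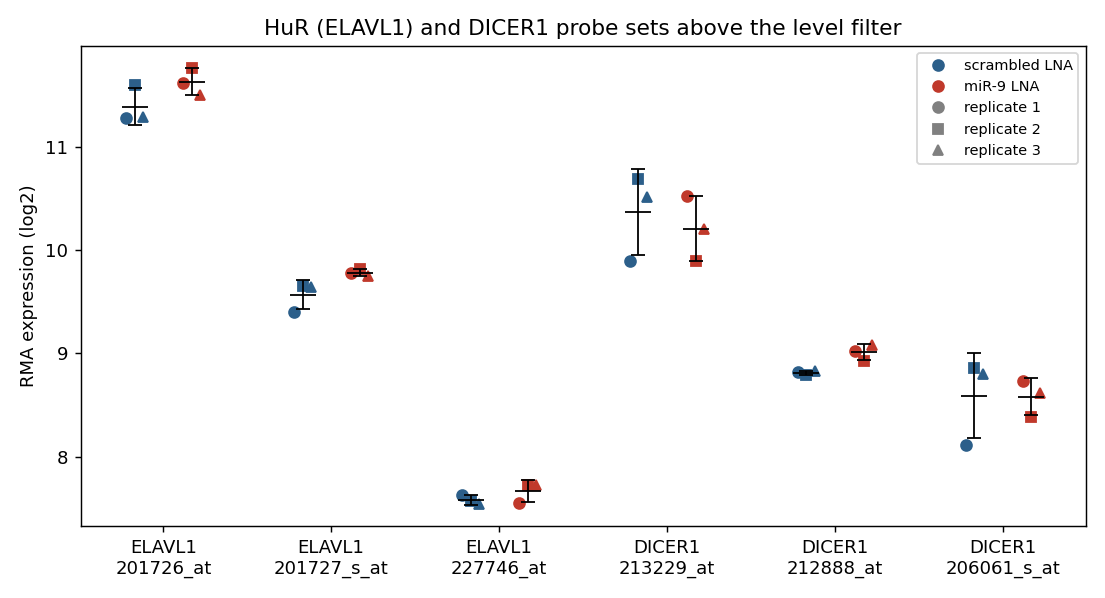
Log2 RMA expression (vertical axis) of the ELAVL1 and DICER1 probe sets above the level filter, per array, for the scrambled LNA (blue) and the miR-9 LNA (red), with marker shapes for the replicate numbers and black bars for the mean and SD of 3 arrays. The groups do not overlap for ELAVL1 201727_s_at and DICER1 212888_at, and they overlap for the other probe sets drawn.

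Across the transcriptome the comparison asks which mRNAs differ when miR-9 is blocked for 9 h. No gene passed the threshold. MDM4, an inhibitor of p53, CTNNB1, which encodes beta-catenin, and RAD50, a DNA repair protein, were among the genes with the smallest p in the higher direction. FCRLA, a B cell protein, and GNB2, a G protein subunit, were among those in the lower direction. Differences were small in both directions, and the higher direction held most of the probe sets with a low p.

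Of 27307 tested probe sets, 0 passed a limma adjusted p under 0.05, and the lowest adjusted p was 0.296. At an unadjusted p under 0.05 limma gave 3926 probe sets, 14.4% of those tested against 1365 expected by chance, of which 3755 were higher with the miR-9 LNA and 171 lower. With replicate number as a block, limma gave 0 probe sets past the threshold and 6218 at an unadjusted p under 0.05, of which 5944 were higher and 274 lower. After quantile normalization limma gave 0 and 1243 probe sets, with 650 higher and 593 lower. The arrays of the groups did not overlap for 4947 probe sets in the higher direction (18.1%) and 1083 in the lower direction (3.97%), where chance gives 5% each way and 10% in all. In simulated arrays of this design with 200 probe sets changed at each size, limma called 23% of those changed by a log2 of 0.3, 63.5% of those changed by 0.5 and 92% of those changed by 1. The simulated noise was independent between probe sets and held no shift shared by an array. These shares may therefore not hold for the real arrays.

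None of the following genes passed the threshold. In the higher direction, MDM4 was at 10.10 ± 0.05 with the miR-9 LNA and 9.71 ± 0.03 with the scrambled LNA, a log2 difference of 0.40 ± 0.06 with a limma adjusted p of 0.296, which the other 7 genes in this direction shared. CTNNB1 was at 10.28 ± 0.04 and 9.86 ± 0.08, a difference of 0.42 ± 0.07. The differences were 0.39 ± 0.06 for EXTL2, 0.34 ± 0.05 for FBXO21, 0.40 ± 0.07 for PRPF4 and 0.34 ± 0.06 for RAD50. TAP2, a peptide transporter of antigen presentation, differed by 0.38 ± 0.07, and PPP1CB, a phosphatase subunit, by 0.44 ± 0.08. After quantile normalization MDM4, CTNNB1, EXTL2, FBXO21, PRPF4, RAD50, TAP2 and PPP1CB kept the higher direction, with differences between 0.19 (RAD50) and 0.26 (PPP1CB).

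In the lower direction, FCRLA was at 7.15 ± 0.02 with the miR-9 LNA and 7.38 ± 0.06 with the scrambled LNA, a log2 difference of -0.23 ± 0.06 (limma adjusted p = 0.296). GNB2 was at 9.76 ± 0.16 and 10.11 ± 0.12, a difference of -0.35 ± 0.10 (limma adjusted p = 0.296), and differed by -0.52 after quantile normalization. The differences were -0.27 ± 0.07 for RHBDL2, -0.26 ± 0.07 for DGKZ, -0.21 ± 0.06 for PLD3, -0.19 ± 0.06 for MUC6, -0.21 ± 0.07 for CELP and -0.24 ± 0.08 for MTA2. FCRLA, RHBDL2, MUC6 and CELP lay within 0.3 of the level filter.

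At an unadjusted p under 0.05, 2 probe sets differed by at least 1.5-fold, and they are named here after their values were seen. FAM76B probe set 1553749_at was at 8.49 ± 0.15 with the miR-9 LNA and 7.73 ± 0.64 with the scrambled LNA, a log2 difference of 0.76 ± 0.28 (limma adjusted p = 0.315). Probe set 201491_at, which has no gene name here, differed by 0.60 ± 0.25 (limma adjusted p = 0.341).

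The size of the difference followed the level of the mRNA. Over 5 equal bins of the tested probe sets from the dimmest to the brightest, the median log2 difference was -0.03, -0.005, 0.06, 0.14 and 0.19. After quantile normalization the same medians were -0.005, -0.007, 0.005, 0.02 and 0.01. The 90th percentile of an array lay between 9.53 and 9.57 with the miR-9 LNA, at 9.45 and 9.47 on scrambled replicates 2 and 3, and at 9.28 on scrambled replicate 1. The group means of this percentile differed by 0.16 (exact permutation p = 0.1, two-sided). The spike-in dap, an added bacterial RNA, was at 10.19 on scrambled replicate 1 and between 8.06 and 8.67 on the other 5 arrays. The spike-ins thr, phe and lys were also highest on scrambled replicate 1, at 8.56, 7.88 and 7.60, against 7.25 to 7.49, 7.17 to 7.48 and 6.95 to 7.27 on the other arrays. Without scrambled replicate 1, limma gave 3597 probe sets at an unadjusted p under 0.05, 76.2% of them higher, against 95.6% with all 6 arrays.

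**Figure D2:**
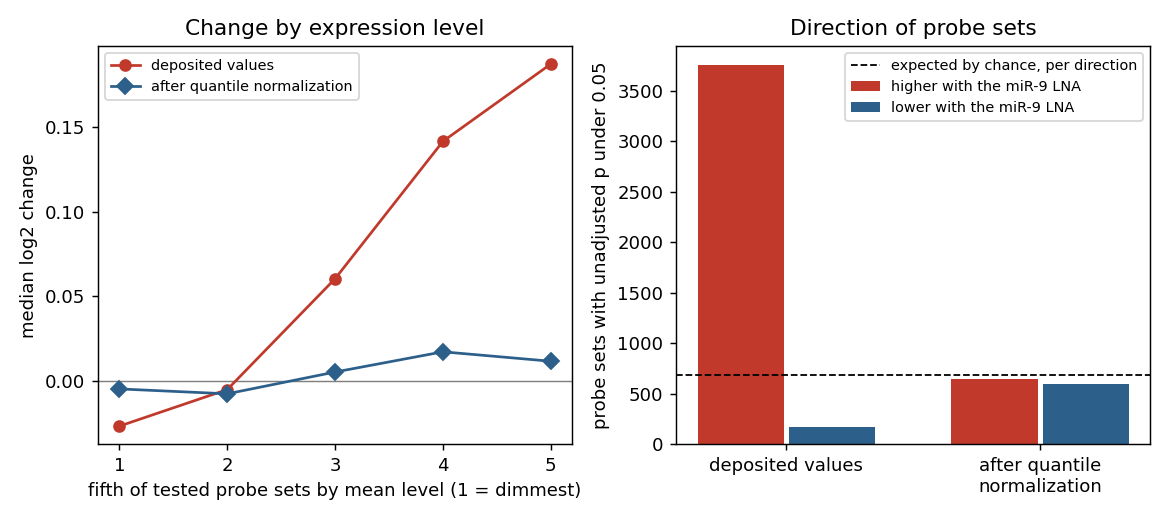
Left, median log2 difference between the miR-9 LNA and the scrambled LNA (vertical axis) in 5 equal bins of the tested probe sets by mean level (horizontal axis, 1 the dimmest), for the deposited values (red) and after quantile normalization (blue). Right, number of probe sets with an unadjusted p under 0.05 that were higher (red) or lower (blue) with the miR-9 LNA, with the number expected by chance per direction as a dashed line: 3755 higher and 171 lower in the deposited values, and 650 and 593 after quantile normalization.

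Blocking miR-9 should release the mRNAs it targets, and HuR binds AU-rich mRNAs that could follow a change of HuR. Neither the reported miR-9 targets nor the reported HuR-bound mRNAs passed against other genes, though the HuR-bound list passed under some other settings. Both lists were mostly higher with the miR-9 LNA in the deposited values, as genes of their level were. The transcription factors FOXO3, NFKB1 and CREB1 led the miR-9 targets by p, and CTNNB1, MCL1 and CCNE1 led the HuR-bound mRNAs.

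The 33 tested reported miR-9 targets had a median log2 difference of 0.14, with 27 higher and 6 lower (limma camera adjusted p = 0.278). That median lay at percentile 56.8 of random lists matched on level. After quantile normalization the median of the miR-9 targets was 0.008, with 20 higher and 13 lower. Among miR-9 targets, FOXO3 differed by 0.32 ± 0.07, NFKB1 by 0.28 ± 0.07 and CREB1 by 0.34 ± 0.10. ELAVL1 and DICER1 are on this list too, and PRDM1, a repressor of B cell identity, differed by 0.20 ± 0.12. Of the miR-9 targets 0 passed over all genes and 0 when adjusted over the list alone. The 27 tested HuR-bound mRNAs had a median of 0.14, with 24 higher and 3 lower (limma camera adjusted p = 0.278) and a level-matched percentile of 26.3. After quantile normalization their median was -0.0006, with 13 higher and 14 lower. The HuR-bound list passed in 3 of 20 alternatives, with no level filter, with the 3'-minus-5' covariate and without scrambled replicate 3, and its limma camera adjusted p ranged from 0.0270 to 0.968. CTNNB1 alone passed among the HuR-bound mRNAs when adjusted over the list alone (limma adjusted p = 0.00769), where 0 passed over all genes. The anti-apoptotic gene MCL1 differed by 0.18 ± 0.07 and the cyclin gene CCNE1 by 0.24 ± 0.11.

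Genes of splicing, mitosis, DNA replication, AU-rich element binding, oxidative phosphorylation, ribosome biogenesis, and microRNA biogenesis and silencing lay higher than other genes with the miR-9 LNA in the deposited values. None of these 7 lists passed once the correlation between a list's genes was estimated, or after quantile normalization, and without scrambled replicate 1 only DNA replication did. Their genes are bright, and random lists of the same level lay about as high. CENPF, HJURP and TPX2 led the mitosis genes, and the exonucleases XRN1 and XRN2 led the microRNA list.

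Of 30 lists, limma camera with a preset correlation of 0.01 put 7 higher and 3 lower at an adjusted p under 0.05. With an estimated correlation limma camera held 0 of these 10 calls, with adjusted p between 0.747 and 0.908. It passed 0 of 30 lists, and the calls it lost include 2 lists with an estimated correlation below the preset one, so their loss does not come from a higher correlation. The other lists called had estimated correlations from 0.102 (cytokines) to 0.578 (oxidative phosphorylation), all above the preset 0.01. After quantile normalization limma camera held 1 of the 10, the cytokines and chemokines. Without scrambled replicate 1 it held 2 of the 10, DNA replication (limma camera adjusted p = 0.00533) and the cytokines (0.00453), while splicing factors were at 0.0634, mitosis genes at 0.0526 and AU-rich element binding proteins at 0.104. Oxidative phosphorylation was then at 0.409, ribosome biogenesis at 0.576 and microRNA biogenesis at 0.553 (limma camera adjusted p). Over all genes 0 members of any list passed. After quantile normalization the members higher with the miR-9 LNA were 28 of 39 splicing factors, 22 of 38 mitosis genes, 25 of 39 DNA replication genes and 18 of 22 AU-rich element binding proteins. They were 19 of 46 oxidative phosphorylation genes, 19 of 33 ribosome biogenesis genes and 20 of 29 genes of microRNA biogenesis and silencing.

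Splicing factors had a median log2 difference of 0.21 over 39 genes, with 36 higher and 3 lower (limma camera adjusted p = 0.00106), at percentile 92.3 of level-matched random lists. Among splicing factors, PTBP2 differed by 0.30 ± 0.07, HNRNPU by 0.22 ± 0.06 and PRPF38B by 0.27 ± 0.07. Mitosis genes had a median of 0.19 over 38 genes, with 37 higher (limma camera adjusted p = 0.00181), at percentile 43.3. CENPF differed by 0.34 ± 0.08, HJURP by 0.30 ± 0.08 and TPX2 by 0.24 ± 0.06. DNA replication genes had a median of 0.17 over 39 genes, with 37 higher (limma camera adjusted p = 0.00488), at percentile 41.6. MCM3 differed by 0.25 ± 0.06, MCM10 by 0.30 ± 0.09 and POLA1 by 0.27 ± 0.09.

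AU-rich element binding proteins had a median of 0.20 over 22 genes, with 21 higher (limma camera adjusted p = 0.0202), at percentile 94.2. Among them PCBP1 differed by 0.23 ± 0.07, RC3H1 by 0.21 ± 0.06 and IGF2BP3 by 0.27 ± 0.08. MicroRNA biogenesis and silencing genes had a median of 0.19 over 29 genes, with 25 higher (limma camera adjusted p = 0.0401), at percentile 94.5. XRN1 differed by 0.31 ± 0.07, XRN2 by 0.27 ± 0.06 and the fragile X protein relative FXR1 by 0.31 ± 0.08. In this microRNA list 6 genes passed when adjusted over the list alone, with a lowest limma adjusted p of 0.0259, and 0 passed over all genes. Adjusting over the list alone does not compare its genes with others of their level, which were also mostly higher. After quantile normalization XRN1 differed by 0.19, XRN2 by 0.10 and FXR1 by 0.12. Ribosome biogenesis genes had a median of 0.18 over 33 genes, with 31 higher (limma camera adjusted p = 0.0205), at percentile 63.7. DDX10 differed by 0.25 ± 0.06, DDX21 by 0.30 ± 0.07 and UTP15 by 0.25 ± 0.07.

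Oxidative phosphorylation genes had a median of 0.16 over 46 genes, with 45 higher (limma camera adjusted p = 0.0202), at percentile 8.29. With replicate number as a block the limma camera adjusted p of oxidative phosphorylation was 0.0592, past the threshold no longer. UQCRC1 differed by 0.29 ± 0.08, NDUFA10 by 0.19 ± 0.06 and SDHA by 0.20 ± 0.07.

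Cytokine and chemokine genes lay lower than other genes with the miR-9 LNA when the correlation between list genes was preset, and did not pass when it was estimated. Hodgkin lymphoma cells secrete many of these proteins, and CCL17, CCL5 and CCL1 were bright in L428. In the deposited values CCL17 and CCL5 differed little between the groups, while CCL1 was higher with the miR-9 LNA by less than its spread. TGFB1 had the lowest p in the lower direction. Markers of T and NK cells and of fibroblasts and endothelium also lay lower than other genes at the preset correlation and not at an estimated one, and their tested members were dim.

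The 22 tested cytokines and chemokines had a median log2 difference of -0.02, with 8 higher and 14 lower (limma camera adjusted p = 0.00488), at percentile 0.01 of level-matched random lists, whose median was 0.10. After quantile normalization the median of the cytokines was -0.10, with 19 of 22 lower (limma camera adjusted p = 0.00966). With an estimated correlation limma camera gave the cytokines an adjusted p of 0.747 in the deposited values and 0.918 after quantile normalization. TGFB1 was at 8.57 ± 0.15 with the miR-9 LNA and 8.85 ± 0.14 with the scrambled LNA, a difference of -0.27 ± 0.10. CSF3 differed by -0.16 ± 0.08 and IL6 by 0.14 ± 0.07. IL6 differed by -0.007 after quantile normalization. CCL17, an attractant of T cells, was at 12.71 ± 0.10 and 12.69 ± 0.14, and CCL5 was at 12.06 ± 0.11 and 12.08 ± 0.35. CCL1 was at 10.64 ± 0.29 and 10.44 ± 0.40, a difference of 0.20 ± 0.22. After quantile normalization CCL17 differed by -0.16, CCL5 by -0.21 and CCL1 by 0.02.

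T and NK cell markers had a median of -0.05 over 7 genes, with 5 lower (limma camera adjusted p = 0.0202), at percentile 20.4 of level-matched lists. CD8B differed by -0.08 ± 0.06, CD5 by -0.08 ± 0.07 and LAT by -0.08 ± 0.07. Fibroblast and endothelial markers had a median of -0.05 over 9 genes, with 6 lower (limma camera adjusted p = 0.0469), at percentile 20.4. FBN1 differed by 0.17 ± 0.06, TEK by -0.08 ± 0.06 and COL1A2 by -0.08 ± 0.07.

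The lists of Hodgkin and Reed-Sternberg cell markers, NF-kB targets, JAK-STAT pathway genes and B cell genes bear on the question of cell identity. None of these lists passed against other genes in the main setting, though the JAK-STAT genes and the Hodgkin markers passed under some others, and the Hodgkin markers and NF-kB targets lay below most random lists of their level. FUT4, which makes the CD15 antigen, and JAK2 led the Hodgkin markers by p, and NFKB1 and REL led the NF-kB targets.

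Hodgkin and Reed-Sternberg cell markers had a median of 0.07 over 27 genes, with 20 higher and 7 lower (limma camera adjusted p = 0.821, direction lower), at percentile 0.02 of level-matched lists. After quantile normalization their median was -0.08, with 8 higher and 19 lower (limma camera adjusted p = 0.275). The Hodgkin markers passed in 1 of 20 alternatives, in the lower direction after quantile normalization and leaving out scrambled replicate 1 (limma camera adjusted p = 0.0104), over a range of 0.0104 to 0.970. FUT4 differed by 0.29 ± 0.09, JAK2 by 0.19 ± 0.07 and IL13RA1 by 0.31 ± 0.13. NF-kB target genes had a median of 0.12 over 30 genes, with 24 higher (limma camera adjusted p = 0.788), at percentile 1.26, where REL differed by 0.25 ± 0.07 and BIRC2 by 0.32 ± 0.12. JAK-STAT pathway genes had a median of 0.13 over 31 genes, with 29 higher (limma camera adjusted p = 0.119), where SOCS4 differed by 0.32 ± 0.10 and SOCS6 by 0.18 ± 0.06. The JAK-STAT list passed in 5 of 20 alternatives, 4 by limma camera and 1 by fry, which does not compare with other genes. Those by limma camera include no level filter (adjusted p = 0.00119) and the SD filter (0.0441), and the adjusted p over the alternatives ranged from 0.00119 to 0.747. B cell identity genes had a median of 0.02 over 19 genes, with 14 higher (limma camera adjusted p = 0.453, direction lower). FCRLA, of the smallest p among them, differed by -0.23 ± 0.06, TCF3 by 0.21 ± 0.06 and HLA-DMA by 0.21 ± 0.07. After quantile normalization these differences were -0.21, 0.02 and 0.03. Plasma cell genes had a median of 0.09 over 15 genes (limma camera adjusted p = 0.821, direction lower), where FKBP11 differed by 0.27 ± 0.11, IRF4 by 0.20 ± 0.08 and CAV1 by 0.22 ± 0.10. Monocyte and granulocyte markers had a median of -0.01 and a mean of 0.008 over 5 genes (limma camera adjusted p = 0.175, direction lower), where CSF3R differed by -0.09 ± 0.07, CTSS by 0.22 ± 0.16 and AIF1 by -0.06 ± 0.08. Interferon response genes had a median of 0.09 over 31 genes, with 26 higher (limma camera adjusted p = 0.495), where SAMD9L differed by 0.27 ± 0.07, PARP9 by 0.30 ± 0.08 and PLSCR1 by 0.29 ± 0.09. limma's fry, which tests whether a list's genes move one way on balance, passed the interferon response and JAK-STAT lists in the higher direction (adjusted p = 0.0326 for each) and 0 of 30 in its mixed test.

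Transfection can stress cells, but both groups were transfected, so this comparison cannot read stress that they share. miR-9 inhibition could alter survival or metabolism. Lists of immediate early, heat shock, unfolded protein, oxidative stress, p53, apoptosis, glycolysis and cholesterol genes did not pass against other genes in the main setting. Some of them, glycolysis most often, passed under other settings. KLF6 led the immediate early genes by p, HSPA4 the heat shock genes, PPM1D the p53 targets and SQLE the cholesterol genes.

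Immediate early genes had a median of 0.09 over 26 genes (limma camera adjusted p = 0.432, direction lower), where KLF6 differed by 0.32 ± 0.09, DUSP6 by 0.20 ± 0.10 and MYC by 0.22 ± 0.11. Heat shock genes had a median of 0.14 over 19 genes (limma camera adjusted p = 0.821, direction lower), where HSPA4 differed by 0.27 ± 0.07, CRYAB by -0.12 ± 0.06 and HSPH1 by 0.23 ± 0.13. Genes of the unfolded protein and amino acid stress response had a median of 0.16 over 36 genes (limma camera adjusted p = 0.383), where SLC7A11 differed by 0.25 ± 0.06, EDEM1 by 0.19 ± 0.06 and SEL1L by 0.18 ± 0.07. Metallothioneins and oxidative stress genes had a median of 0.13 over 22 genes (limma camera adjusted p = 0.278), where SRXN1 differed by 0.27 ± 0.07 and GCLM by 0.24 ± 0.07. p53 target genes had a median of 0.10 over 23 genes (limma camera adjusted p = 0.880, direction lower), where PPM1D differed by 0.23 ± 0.06, TP53INP1 by -0.17 ± 0.06 and SESN1 by 0.17 ± 0.08. Apoptosis regulators had a median of 0.11 over 25 genes (limma camera adjusted p = 0.929), where BIRC2 differed by 0.32 ± 0.12 and BCL2L11 by -0.17 ± 0.08. Of 20 alternatives, the unfolded protein list passed in 4 (lowest limma camera adjusted p 0.0155), the oxidative stress list in 1 (0.0195), the heat shock list in 1 (0.0429) and the immediate early genes in 1 (0.00540, lower, without miR-9 LNA replicate 3), and the p53 and apoptosis lists in 0.

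Glycolysis and hypoxia genes had a median of 0.17 over 34 genes, with 29 higher (limma camera adjusted p = 0.203, and 0.0423 with replicate number as a block, which passes). The glycolysis list passed in 6 of 20 alternatives, over limma camera adjusted p of 0.00256 to 0.989, and was at 0.966 with an estimated correlation and 0.739 after quantile normalization. KDM3A differed by 0.26 ± 0.06, ENO2 by 0.25 ± 0.06 and PFKP by 0.24 ± 0.06. Cholesterol biosynthesis genes had a median of 0.13 over 19 genes (limma camera adjusted p = 0.821), where SQLE differed by 0.29 ± 0.09, PMVK by 0.17 ± 0.07 and IDI1 by 0.20 ± 0.10. Cytosolic ribosomal protein genes had a median of 0.13 over 51 genes, with 51 higher (limma camera adjusted p = 0.212), where RPL27A differed by 0.32 ± 0.15, RPLP2 by 0.17 ± 0.09 and RPL14 by 0.18 ± 0.09. The ribosomal protein genes lay at percentile 0.07 of level-matched lists in the deposited values, and their median was -0.009 after quantile normalization, at percentile 79.6 of lists then matched on level and gene length. Replication-dependent histones had a median of 0.003 over 18 genes, with 9 higher and 9 lower (limma camera adjusted p = 0.0970, direction lower), where H2BC12 differed by 0.22 ± 0.13, H1-2 by 0.19 ± 0.13 and H4C5 by -0.07 ± 0.06. Common reference genes had a median of 0.17 over 13 genes, with 13 higher (limma camera adjusted p = 0.0970), where GUSB differed by 0.26 ± 0.09, TBP by 0.20 ± 0.07 and SDHA by 0.20 ± 0.07. The median of the reference genes was 0.01 after quantile normalization, with 9 higher and 4 lower, and 0.04 without scrambled replicate 1.

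**Figure D3:**
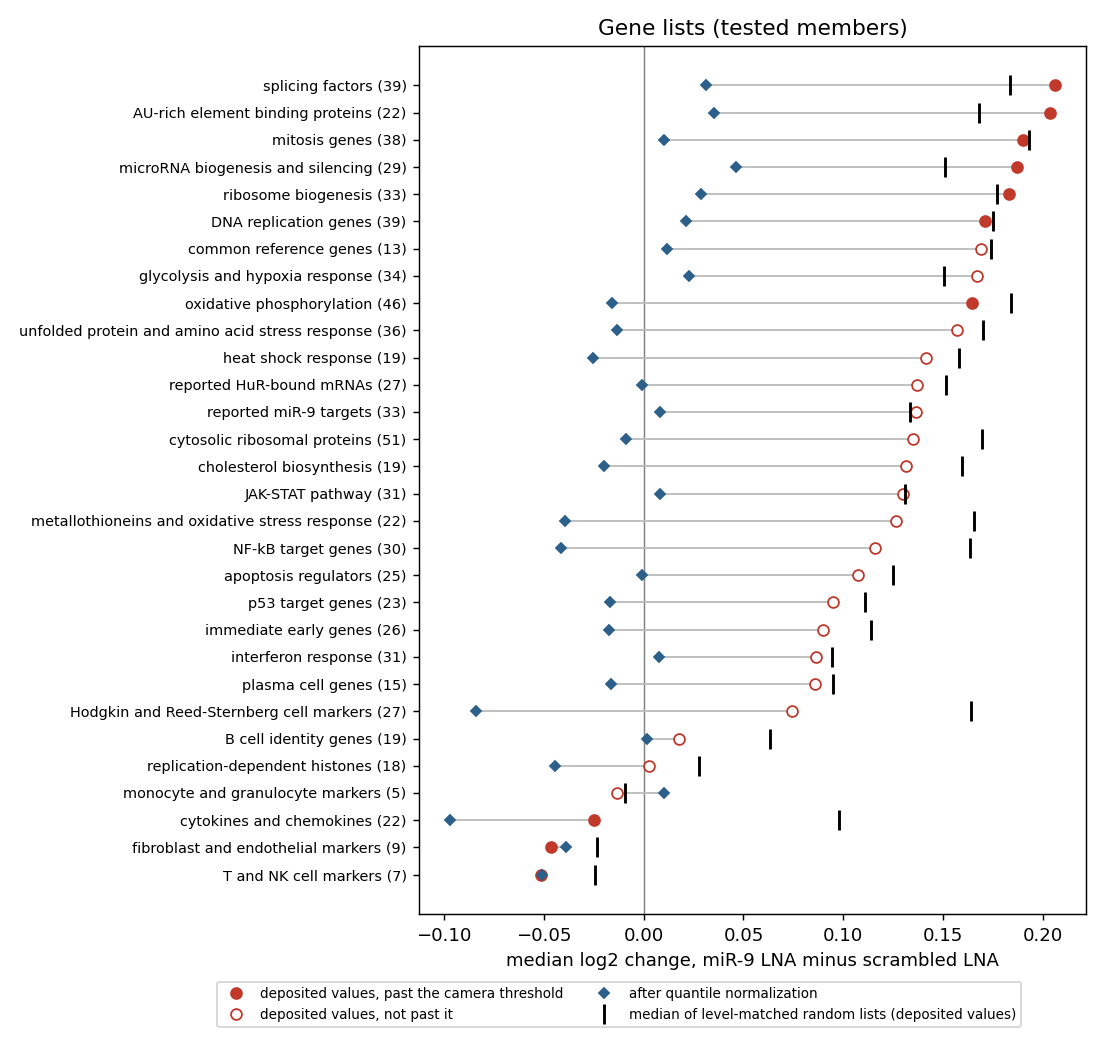
Median log2 difference between the miR-9 LNA and the scrambled LNA (horizontal axis) of each gene list (vertical axis, tested members in parentheses) in the deposited values (red, filled where limma camera passed the threshold) and after quantile normalization (blue), with the median of level-matched random lists of the deposited values as a black tick. The cytokines and chemokines lay at -0.02 against 0.10 for level-matched lists, and splicing factors at 0.21 against 0.18.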

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

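Quantile normalization joined with the replicate block or with leaving out scrambled replicate 1, and the level-matched lists, were alternatives chosen after the data were examined. Under each alternative 0 probe sets passed a limma adjusted p under 0.05, with the lowest adjusted p between 0.121 (array weights) and 0.900 (quantile normalization). The next counts leave out the fits without each array in turn, but include quantile normalization followed by leaving out scrambled replicate 1. The ELAVL1 and DICER1 probe sets kept their direction in 106 values and reversed in 4, and the named genes in 1243 and 13. None of these passed in any setting, so their side of the threshold did not change. Changes of filter, variance model and replicate block leave a probe set's difference as it was, so part of this agreement was fixed in advance. The lists kept their direction and side of the threshold in 271 values, with 66 that no longer passed, 23 that newly passed and 57 whose test direction reversed. The cause of a difference was not tested unless one is given. Counts below are probe sets with an unadjusted p under 0.05 (3755 higher and 171 lower in the deposited values) and lists past limma camera's threshold (7 higher and 3 lower), list values are median log2 differences where the test direction reversed, and a median can keep its sign when the test, which compares with other genes, does not. With no level filter, 1032 probe sets were lower and 14 lists higher, and the medians were 0.0651 for immediate early genes, 0.142 for heat shock genes, 0.0887 for p53 targets, 0.0650 for Hodgkin and Reed-Sternberg cell markers and 0.0795 for plasma cell genes. With the filter at the 60th percentile, which tests fewer probe sets, 67 were lower, 2 lists were higher and 1 lower, with medians of 0.121 for NF-kB targets, 0.109 for apoptosis regulators and 0.131 for cholesterol genes. With the upper part of probe sets by SD, 100 were lower and 12 lists higher, with medians of 0.145 for heat shock genes, 0.0849 for Hodgkin markers and 0.0930 for plasma cell genes. With median centring 65 were lower, DICER1 206061_s_at differed by 0.0141 and the apoptosis regulators had a median of 0.134. With quantile normalization 650 probe sets were higher and 593 lower, with 0 lists higher and 1 lower, the cytokines. IL6 then differed by -0.00699, MCL1 by -0.000614, SEL1L by -0.0166 and IDI1 by -0.000424. The medians after quantile normalization were -0.0415 for NF-kB targets, -0.0135 for the unfolded protein response, -0.000614 for apoptosis regulators, -0.0196 for cholesterol genes, -0.00889 for ribosomal proteins, -0.0160 for oxidative phosphorylation and -0.0392 for metallothioneins and oxidative stress. Quantile normalization with the replicate block reversed the same genes and lists with the same differences, and gave 1767 probe sets higher and 1143 lower, with 0 lists higher and 1 lower. Quantile normalization of the 6 arrays followed by leaving out scrambled replicate 1 gave 816 probe sets higher, 1353 lower and 0 lists higher. There DICER1 216281_at differed by 0.0128, ELAVL1 244660_at by -0.00179, MYC by -0.00700, HSPH1 by -0.0284, H2BC12 by -0.00438 and IDI1 by -0.0415. Its medians were -0.0129 for NF-kB targets, -0.0189 for HuR-bound mRNAs, -0.0350 for the unfolded protein response, 0.00172 for apoptosis regulators, -0.0430 for cholesterol genes, -0.0217 for ribosomal proteins, 0.00144 for oxidative phosphorylation, -0.0200 for ribosome biogenesis and -0.000484 for metallothioneins and oxidative stress. With trend and robust eBayes 355 were lower and 4 lists higher. With array weights 1183 were lower, 4 lists were higher and 1 lower, with medians of 0.0718 for NF-kB targets, 0.0614 for apoptosis regulators, 0.0788 for cholesterol genes and 0.0217 for ribosomal proteins. With the replicate block 5944 were higher and 274 lower, and the medians were 0.0896 for immediate early genes, 0.142 for heat shock genes, 0.0950 for p53 targets and 0.0856 for plasma cell genes. Besides oxidative phosphorylation and glycolysis, the replicate block changed no other call. With the 3'-minus-5' covariate 266 were lower, 11 lists higher and DICER1 206061_s_at differed by 0.0151, with medians of 0.129 for immediate early genes, 0.178 for heat shock genes, 0.121 for p53 targets, 0.118 for Hodgkin markers and 0.112 for plasma cell genes. With 1 probe set per gene, which tests fewer items, 2259 were higher and 73 lower. With the mean of a gene's probe sets, fewer items again, 1740 were higher, 98 lower and 4 lists higher, BCL2L11 differed by 0.00406, and the medians were 0.0786 for NF-kB targets and 0.0855 for p53 targets. Without _x_at and _s_at probe sets, again fewer, 2424 were higher. At least 1.5-fold, 2 were higher and 0 lower. With an estimated correlation 0 lists were higher and 0 lower. With fry, which does not compare with other genes, 2 lists were higher and 0 lower, and lists whose direction it reversed had medians of 0.0896 for immediate early genes, 0.142 for heat shock genes, 0.0950 for p53 targets, 0.00278 for histones, 0.0745 for Hodgkin markers, 0.0179 for B cell genes and 0.0856 for plasma cell genes. Against level-matched lists 0 lists lay above the central 95% of the random medians. Below it lay the cytokines (percentile 0.01), Hodgkin markers (0.02), ribosomal proteins (0.07) and NF-kB targets (1.26). The T and NK cell markers and the fibroblast and endothelial markers, both called lower by limma camera, lay within it (20.4 each). Leaving out each array in turn gave 2303 to 4163 probe sets higher, 42 to 856 lower, 1 to 12 lists higher and 1 to 3 lower. The 1 higher, 1 lower and 856 came without scrambled replicate 1, the 2303 without miR-9 LNA replicate 1, the 42 without miR-9 LNA replicate 2 and the 12 without scrambled replicate 3. Ranges over the arrays left out were -0.25 to 0.12 for DICER1 206061_s_at, -0.40 to 0.000282 for DICER1 213229_at and -0.0194 to 0.19 for ELAVL1 244660_at. The medians of lists whose direction reversed ranged from -0.0462 to 0.210 for immediate early genes, -0.0297 to 0.234 for heat shock genes, 0.0431 to 0.163 for p53 targets, 0.00857 to 0.197 for ribosomal proteins, 0.0379 to 0.161 for Hodgkin markers, 0.0208 to 0.183 for plasma cell genes, 0.0601 to 0.180 for NF-kB targets, 0.0371 to 0.218 for the unfolded protein response, 0.05001 to 0.160 for apoptosis regulators, 0.0366 to 0.237 for cholesterol genes and 0.0510 to 0.197 for HuR-bound mRNAs. Of the 10 lists called, 2 were called without scrambled replicate 1 and 6 to 10 without another array. Lists that newly passed were, with no level filter, HuR-bound mRNAs, unfolded protein response, histones (lower), glycolysis, ribosomal proteins, monocyte markers (lower), JAK-STAT, oxidative stress and reference genes, with limma camera adjusted p from 0.00087 to 0.0425. With the SD filter they were unfolded protein response, glycolysis, ribosomal proteins, JAK-STAT and reference genes, and with the 3'-minus-5' covariate HuR-bound mRNAs, unfolded protein response, glycolysis and JAK-STAT. Glycolysis passed with the replicate block, interferon response and JAK-STAT with fry, and heat shock genes (0.0429) and Hodgkin markers (0.0104), both lower by limma camera, after quantile normalization and leaving out scrambled replicate 1. Leaving out arrays gave 11 further new calls. They were histones (lower), glycolysis and JAK-STAT without miR-9 LNA replicate 1, immediate early genes (lower) without miR-9 LNA replicate 3, and ribosomal proteins and reference genes without scrambled replicate 2. Without scrambled replicate 3 they were HuR-bound mRNAs, unfolded protein response, glycolysis, ribosomal proteins and reference genes, with limma camera adjusted p from 0.00420 to 0.0416. The miR-9 seed site test and its alternatives were not run. Dim genes near the background limit what a difference can show.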

Other observations

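A family of centrosomal protein (CEP) genes, which build the poles of the dividing cell, lay higher than other genes with the miR-9 LNA at the preset correlation. With an estimated correlation the family did not pass, with limma camera adjusted p of 0.750 in the deposited values and 0.971 after quantile normalization. CEP152 and CEP135, which act in centriole duplication, had log2 differences of 0.30 ± 0.06 and 0.30 ± 0.07, and CEP57 one of 0.27 ± 0.07. The markers of Hodgkin and Reed-Sternberg cells lay below genes of their level, at percentile 0.02 of level-matched random lists, and the NF-kB targets at percentile 1.26. The Hodgkin list shares 3 tested genes with the cytokines, and without them its remaining 24 genes lay at percentile 0.38. Without 5 shared with the cytokines or the Hodgkin list, the remaining 25 NF-kB targets lay at percentile 6.02. These percentiles describe the 6 arrays and carry no test between groups of samples.

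The family tests, list percentiles and spike-in test here were chosen after the data were examined. Quantile normalization, leaving out each array and the estimated correlation had been fixed as alternatives before, but their use as tests of an explanation was chosen after their results were seen. This holds for quantile normalization and the array left out on the excess of higher probe sets, for quantile normalization and estimated correlation on the cytokines, and for quantile normalization on the CEP genes. The counts over splits for probe sets and for lists were chosen after as well.

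The excess of probe sets higher with the miR-9 LNA was 95.6% of those with an unadjusted p under 0.05. The 3'-minus-5' difference of the GAPDH and ACTB controls, a sign of RNA degradation, was 0.26 ± 0.18 with the miR-9 LNA. With the scrambled LNA it was 0.22 ± 0.15 (exact permutation p = 0.6, two-sided), so degradation as read by these controls did not part the groups. The share was 95.4% with that difference as a covariate, but a covariate so alike in both groups could scarcely change it. Scrambled replicate 1 as the whole source is argued against, since 76.2% of the probe sets at an unadjusted p under 0.05 without it were higher. A difference in the level scale of the arrays stays open. After quantile normalization the share was 52.3%, but this normalization gives each array the same distribution and so largely sets the share itself. A test on the spike-ins was therefore added after that result was seen. The 18 hybridization spike probe sets, by usual practice added to each array in equal amounts, differed by 0.0473 between the groups, against 0.15 for 11001 tested probe sets in their level range. The gap of 0.10 ± 0.07 (SE over the arrays) is within 2 standard errors, so the spike-ins do not settle whether hybridization or scanning is the source. The spike-ins dap, thr, phe and lys were highest on scrambled replicate 1, so a smaller amount of sample RNA on that array also stays open, as untested. An effect of miR-9 inhibition on mRNA amounts is open and untested. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets, the real one, with 3926 against 2293 for the highest other, and 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 same-numbered pairs, the real one gave 3926 and the highest other 807, while the other 6 splits keep 1 pair together on each side.

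The cytokine and chemokine genes were lower than other genes. After quantile normalization limma camera at the preset correlation gave an adjusted p of 0.00966. The cytokines were the 1 list of the 10 called that held there, and this use was chosen after that result was seen. The value thus repeats the choice and does not decide on a difference in level scale. Gene length and level are argued against, since the list lay at percentile 0.01 of random lists matched on both after quantile normalization. Variation shared by the list's genes stays open. The estimated correlation of the cytokines was 0.102, above the preset 0.01, so their call rests on a correlation below the estimated one. limma camera's adjusted p was 0.747 with an estimated correlation, and 0.918 with it after quantile normalization. That setting passed 0 of 30 lists and ended the calls of 2 lists whose estimated correlation lay below the preset one. Its adjusted p therefore does not decide on shared variation. Of the 10 splits, 3 gave as small a camera p after quantile normalization, where the real split gave 0.000322 and the smallest of the others 8.68e-06. Both splits with a smaller p keep a same-numbered pair together, and among the 4 splits that part all pairs the real one gave 0.000322 and the smallest of the others 0.00853. Both 4 and 10 splits are too few for a share under 0.05. The pairing was read from the same arrays, with r of 0.231 and 0.193 for pairs 1 and 2 against up to 0.168 for other numbers. It is thus a weak ground for setting splits aside. A response of cytokine mRNAs to miR-9 inhibition stays open and untested. For the number of lists past the threshold, 6 of the 10 splits gave as many, with 10 for the real split and 15 for the highest other, and among the 4 splits that part all pairs 10 for the real one and 10 for the highest other. The splits with 13, 14 and 15 lists each keep a same-numbered pair of arrays together, so the list calls also follow structure among the arrays other than their group.

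The CEP family came from 84 families of genes sharing a symbol stem with at least 15 tested members. Of these, 10 passed limma camera in the deposited values and 1, CEP, passed after quantile normalization too. Its 31 genes had a median log2 difference of 0.17, with 29 higher, and 0.08 after quantile normalization, with 27 higher. Its limma camera adjusted p over the families was 0.000396 after quantile normalization. As the family was singled out for passing there, this value repeats the choice, and a difference in level scale stays open. CEP genes are long, with a median of 64116 bp against 27253 bp for all genes, and differences after quantile normalization followed gene length across genes (Spearman's rho 0.268, with genes not independent replicates). The family lay at percentile 99.9 of lists matched on length and level. That percentile is not adjusted for the choice among 84 families, so length and level stay open too. Shared variation of the family's genes stays open, since limma camera's adjusted p of 0.971 with an estimated correlation after quantile normalization comes from a setting that passed 0 of 84 families. Of the 10 splits, 1 gave as small a camera p, the real one, with 4.71e-06 against 0.000373 for the next, which also parts all pairs, and 10 splits are too few for a share under 0.05. The family was chosen on the real split, which favours that split here. The CEP pattern is a hypothesis, found and tested on the same 6 arrays.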
